A study of Mus musculus with 24 samples.

How the data were processed

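Gene expression was measured by RNA sequencing of total RNA from the gastrocnemius muscle of mice. Per the labels' extraction protocol, the muscle was frozen in liquid nitrogen, broken up with a bead homogenizer in Trizol, and the RNA was purified on Qiagen columns. The deposited values are whole-number read counts per Ensembl gene ID, not normalized, in 3 tables: 1 for transgene females, 1 for flox females and 1 for all males. Per the submitters' processing notes, STAR, featureCounts and limma were used and the builds named are GRCm38 and mm10, without versions, roles or order. The library kit, the strand setting of the counting, the treatment of reads that map to several places, the annotation release, and the dose and timing of tamoxifen are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical gene copies are therefore uncertain.

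Of 54752 gene IDs, 54723 were matched to a symbol and 29 were not, and 33803 had a count in some library. Coordinates are those of the GENCODE annotation of GRCm38. Libraries held 21516819 to 43014516 counts. The 24 pairs of replicates within groups differed by more than sampling noise, with a chi-square per degree of freedom of 9.22 to 117, so no library was treated as a duplicate. Replicates carry separate numbers in the labels, which do not state that each is a separate animal; the p-values measure the spread between these libraries.

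Each library was assigned to 1 of 8 groups of 3 by sex, transgene and treatment from its labels. For 3 male transgene libraries the title says vehicle control and the treatment field says tamoxifen; they were grouped by title, together with the design text, which crosses tamoxifen treatment with the transgene. The 6 flox male libraries are titled WT while their genotype field gives the floxed alleles, and they were grouped by that field. Tests were run in R 4.3.3 with edgeR 4.0.16: TMM scaling, a filter on low counts (filterByExpr, minimum count 10 and minimum total count 15), robust dispersion estimates and the quasi-likelihood F-test, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes are from this test unless another tool is named. The standard error of a log2 fold change was taken as its size divided by the square root of F. Tamoxifen was compared with vehicle in transgene females, in flox females, in transgene males and in flox males. Transgene and flox males were compared after vehicle. In each sex the difference between the transgene and flox responses was tested as an interaction, and the responses of transgene animals were tested over both sexes and for a difference between the sexes. Female comparisons within a genotype used the 6 libraries of their own table, and male comparisons used all 12 male libraries. Transgene and flox females lie in different tables, so genotype and table cannot be told apart in females and their vehicle groups were not compared. A female against male difference of the flox responses was added after the data were seen. CPM given with a comparison were computed with library sizes TMM-scaled over the libraries in its fit. All other CPM, such as those per library, used TMM scaling over all 24 libraries.

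Genes named in the text were chosen by a rule set before the data were examined. Numb and Numbl were always named. For each comparison the rule took the 10 largest rises and 10 largest falls among genes at an adjusted p under 0.05 with a mean log2 CPM of at least 0, a symbol that is not a clone or predicted-model name and, for comparisons of groups, no overlap between the groups. It added up to 4 members past the threshold from each of 32 gene lists, and the 3 smallest p-values where a comparison had no gene past the threshold. Some results that this rule selects are not reported here. The lists cover muscle, metabolic, stress and signalling genes and markers of other cell types in muscle. They were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, again with an estimated correlation, and with fry. With the preset correlation camera called between 5 and 15 lists per comparison and with an estimated correlation 0, so no list call given here holds under that estimate. Other groupings of the same libraries often called as many lists with the preset correlation.

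The procedure was tested on simulated data with 200 changed genes per comparison, drawn from the mean, dispersion and library size of the real data. Of genes changed 2-fold, it recovered 69.7% in transgene females, 72.3% in flox females, 59.1% in transgene males, 60.6% in flox males and 68.7% between vehicle males. For the interactions these shares were 45.5% in females and 40.9% in males. They were 72.6% over both sexes, 40.0% for the difference between transgene sexes and 43.9% for that between flox sexes. Of genes changed 1.5-fold, 20.6%, 30.8%, 21.0%, 21.5%, 21.9%, 10.6%, 1.56%, 31.8%, 3.12% and 12.3% were recovered in the same order, and false calls made up 2.46% to 9.21% of all calls. Each gene was drawn independently, so these rates leave out variation that genes share between real libraries and may not carry over. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no low-count filter, a stricter filter on mean CPM, other sets of libraries in the fit and leaving out each library in turn. Added after the data were seen were fits without 2 transgene male libraries low in the slow fibre gene Myh7, and a fit with the 3 transgene male libraries lowest in Myh7 as a block; both choose libraries by a value measured in them. No deposited sample column was left out.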

Results

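RNA was sequenced from the gastrocnemius, the large calf muscle, in 24 mouse libraries that form 8 groups of 3. Per the genotype labels all animals carried floxed alleles of Numb and Numbl, which encode adaptor proteins of endocytosis known as regulators of Notch signalling. Animals of 4 groups also carried MerCreMer, a Cre recombinase that tamoxifen activates, under the human skeletal actin promoter, which is active in muscle fibres. The other 4 groups lacked the transgene and are called flox animals here, although the titles of the 6 males among them read WT. Females and males of both genotypes received vehicle or tamoxifen, so that tamoxifen in transgene animals is the conditional knockout and tamoxifen in flox animals shows the drug without the recombinase. Libraries held 31219445 to 39142101 counts in transgene females, 36099031 to 43014516 in flox females and 21516819 to 29982077 in males. The most counted gene was Myh4, the fast myosin heavy chain, in all 24 libraries, with 4.91% to 9.27% of counts.

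Numb and Numbl were read first in every library. Numb (chromosome 12, 83794034 to 83921934, minus strand, GRCm38) lay between 15.3 and 25.3 CPM in the 24 libraries. In transgene females it had a mean of 22.6 ± 1.64 CPM (SD, n = 3) after vehicle and 19.0 ± 0.0747 after tamoxifen, and in flox females 23.0 ± 2.13 and 18.9 ± 1.27. Transgene males had 19.0 ± 1.36 and 19.0 ± 1.56 CPM, and flox males 18.7 ± 1.62 and 15.9 ± 0.584. Numbl (chromosome 7, 27258433 to 27282144, plus strand) lay between 2.67 and 6.49 CPM. Its means after vehicle and tamoxifen were 3.22 ± 0.598 and 4.37 ± 0.682 CPM in transgene females, 2.87 ± 0.0895 and 3.80 ± 0.358 in flox females, 2.98 ± 0.192 and 3.76 ± 0.869 in transgene males and 3.89 ± 0.432 and 5.57 ± 0.803 in flox males. The log2 change of Numb with tamoxifen was -0.24 ± 0.08 (SE; adjusted p = 0.187, edgeR quasi-likelihood test) in transgene females and 0.00 ± 0.10 (adjusted p = 1) in transgene males. In flox animals it was -0.28 ± 0.10 (adjusted p = 0.452) in females and -0.23 ± 0.10 (adjusted p = 0.233) in males. For Numbl the changes were 0.45 (adjusted p = 0.28), 0.34 (adjusted p = 0.594), 0.41 (adjusted p = 0.498) and 0.51 (adjusted p = 0.153) in the same order of transgene and flox animals. Counts per whole gene do not separate the floxed part of a transcript from the rest, so these values neither show nor exclude recombination, and both genes overlap exons of other annotated genes.

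Other genes checked the labels. Esr1, the oestrogen receptor gene whose ligand-binding domain MerCreMer carries, lay at 399 to 1950 CPM in the 12 transgene libraries and at 22.8 to 42.1 CPM in the 12 flox libraries. Xist, the RNA of the inactive X chromosome, lay at 111 to 199 CPM in females and at most at 0.278 CPM in males, and the Y-linked Ddx3y at 68.8 to 103 CPM in males and at most at 0.0283 in females. For 3 transgene male libraries the title names a vehicle control and the treatment field names tamoxifen. They are treated as vehicle animals by their titles, and each comparison with transgene vehicle males rests on that reading. Flrt1, a leucine-rich repeat transmembrane protein, lay at 3.26 to 3.68 CPM in these 3 libraries, at 1.67 to 2.31 CPM in flox vehicle males and at 169 CPM or more in the 3 male libraries titled cKO and the 3 titled WT tam.

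**Figure D1:**
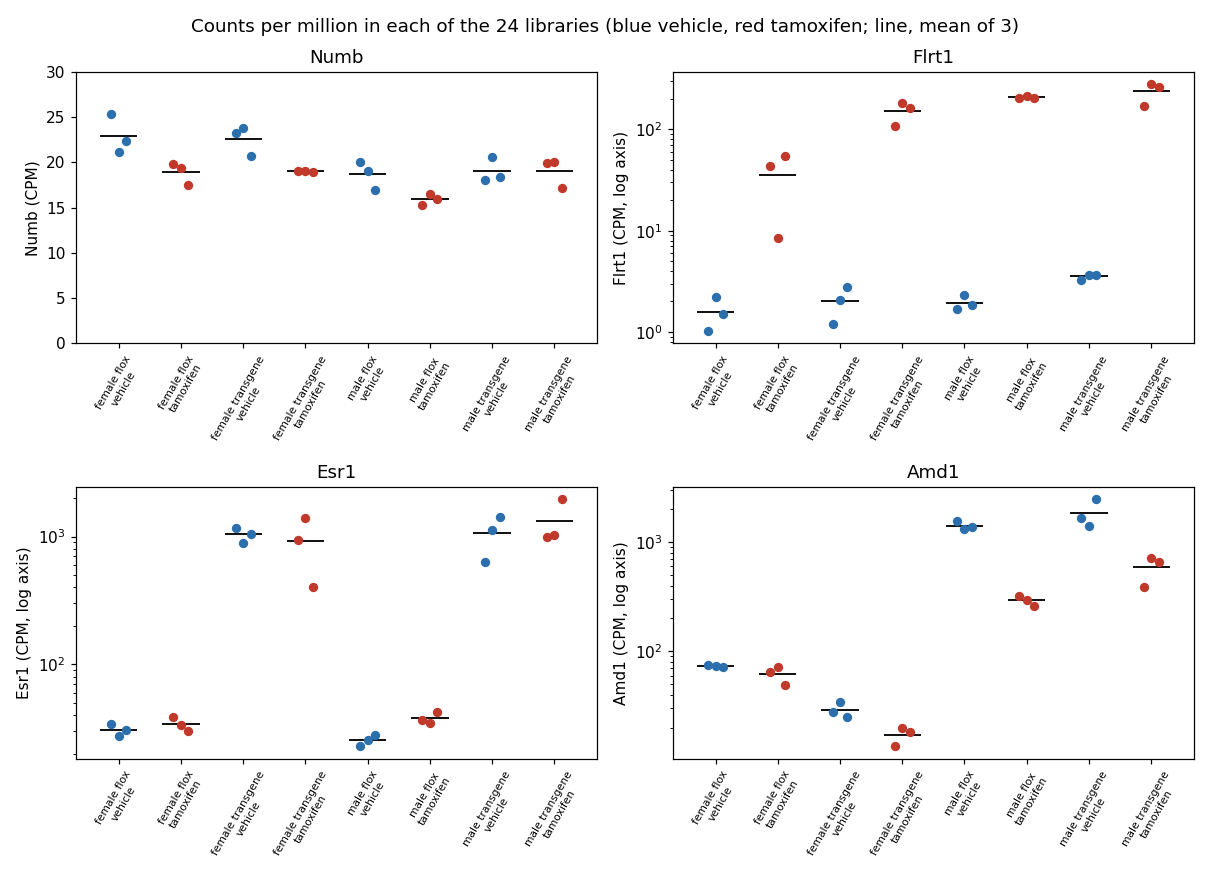
CPM of Numb (linear axis) and of Flrt1, Esr1 and Amd1 (log axes) in each of the 24 libraries by group, with vehicle in blue, tamoxifen in red and a line at each mean of 3. Esr1 separates the 12 transgene libraries (399 CPM or more) from the 12 flox libraries (42.1 CPM or less), while Numb lies between 15.3 and 25.3 CPM throughout.

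In transgene females tamoxifen raised Flrt1 (chromosome 19, 7092001 to 7105729) from 2.04 ± 0.808 to 154 ± 40.0 CPM (SD, n = 3), a log2 change of 6.23 ± 0.37 (SE; adjusted p = 0.00416). Rhpn2 rose by 2.01 ± 0.16, the synaptic adhesion gene Lrfn4 by 1.76 ± 0.21, and the potassium channel subunit gene Kcne1l by 3.52 ± 0.45. The integrin subunit gene Itga4 fell by 1.90 ± 0.17, the small GTPase gene Rasd2 by 1.78 ± 0.19, and Dusp10, a phosphatase of MAP kinases, by 1.46 ± 0.13. Of 14211 genes tested, 187 passed the threshold, 87 higher and 100 lower after tamoxifen, 59 of them at least 2-fold. In 22.6% of genes the groups did not overlap, against 10% by chance.

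Among the 18 clock genes measured in transgene females, 2 rose, 3 fell and 13 did not pass over all genes. Arntl, the clock activator also called Bmal1, fell by 1.74 ± 0.24 (adjusted p = 0.0353) and the clock repressor gene Cry1 fell by 0.55 ± 0.11, while Ciart rose by 1.69 ± 0.29 and Hlf by 0.88 ± 0.16. Adjusted over the list alone, 7 rose and 6 fell, with Per2 at 2.02 and Npas2 at -1.24, and camera found no one-sided shift (adjusted p = 0.631; adjusted p = 0.892 with an estimated correlation). In the denervation and atrophy list 2 of 25 rose, Map1lc3a of autophagy by 0.65 ± 0.07 and the transcription factor gene Foxo3 by 0.44 ± 0.08. Adjusted over the list alone 6 rose, among them the acetylcholine receptor subunit gene Chrnd at 0.76, and 1, Myog, a myogenic transcription factor gene, fell by 0.81 (camera up, adjusted p = 0.011; adjusted p = 0.762 with an estimated correlation). Single members fell in the sarcomere and costamere list (Xirp2, by 0.63 ± 0.10), the calcium handling list (Mrln, a regulator of the calcium pump, by 0.76 ± 0.12), the glycolysis and glycogen list (Phka1, a phosphorylase kinase subunit, by 0.91 ± 0.16) and the unfolded protein list (the chaperone gene Hsph1, by 1.01 ± 0.16). Adjusted over each list alone, 1 sarcomere gene rose (Tcap) and 2 fell, 3 glycolysis genes fell, and 1 calcium handling gene fell. In the unfolded protein list 3 rose by that adjustment, Trib3 at 1.16, Xbp1 at 0.39 and Dnajb9 at 0.37, and 1 fell. The calcium handling list had a median of -0.11, a mean of 0.04 and a direction of down at an adjusted p of 0.0741. Of 17 interferon response genes 0 passed over all genes in edgeR's test and 5 fell when adjusted over the list alone, among them Oasl2 at -1.13 and Stat2 at -0.67 (camera down, adjusted p = 2.82e-05; adjusted p = 0.762 with an estimated correlation). The adipocyte markers had 1 rise of 14, Plin4 of lipid droplets at 0.71 ± 0.13, and 3 when adjusted over the list alone (camera up, adjusted p = 0.00083; adjusted p = 0.762 with an estimated correlation). Slow fibre genes had a median log2 change of 0.76 with 0 of 15 members past the threshold in edgeR's test by either adjustment (camera up, adjusted p = 0.00623; adjusted p = 0.762 with an estimated correlation). Myh7, the slow myosin gene, lay at 335 to 1730 CPM in the vehicle and 1090 to 2660 CPM in the tamoxifen libraries of these females. Of 27 Notch signalling genes, 28 Numb partners and endocytic adaptors and 11 septins, 0 passed the threshold by either adjustment in edgeR's test, and camera gave adjusted p = 0.548, 0.734 and 0.298. Without vehicle library 1 or 2 the count of 187 was 37 or 55. Without tamoxifen library 1 or 3 it was 61 or 112, and DESeq2 gave 679. Of 29 calls chosen by the naming rule in these females, 8 held in all 12 alternatives and 21 were lost in some. Ciart was lost in 7, Foxo3 in 6 and Arntl in 5. Rhpn2, Arntl, Itga4, Xirp2, Bhlhe40 and Plin4 overlap exons of other genes, so their counts are uncertain.

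In flox females, where tamoxifen meets no recombinase, Per1, a clock repressor, rose from 40.3 ± 5.93 to 149 ± 19.0 CPM (SD, n = 3), a log2 change of 1.89 ± 0.13 (SE; adjusted p = 0.00117), and Ciart rose by 2.37 ± 0.24. Coq10b of coenzyme Q metabolism rose by 1.51 ± 0.16, the DNA repair gene Xrcc2 by 1.25 ± 0.11 (adjusted p = 0.00275) and Usp2, a deubiquitinase, by 0.85 ± 0.11. Smarca1, a chromatin remodeller, fell by 1.08 ± 0.14. The test called 19 of 14539 genes, 14 higher and 5 lower, and groups did not overlap in 14.5% of genes (10% by chance). Flrt1 lay at 1.02 to 2.23 CPM after vehicle and at 8.56 to 54.3 CPM after tamoxifen, a log2 change of 4.48 ± 0.92 that did not pass (adjusted p = 0.368). Of 18 clock genes 2 rose over all genes, and adjusted over the list alone 8 rose, such as Per2 at 1.44 and Dbp at 1.16, and 3 fell, such as Arntl at -0.95 (camera up, adjusted p = 0.000747; adjusted p = 0.885 with an estimated correlation). Of 20 immediate early genes 1 rose over all genes, Fosl2 by 0.80 ± 0.10, and 5 when adjusted over the list alone, with Nr4a2 at 1.85, Fosb at 1.65 and Junb at 0.96 (camera up, adjusted p = 4.67e-05; adjusted p = 0.885 with an estimated correlation). The 39 nuclear genes of oxidative phosphorylation had a median change of 0.11 with 0 members past the threshold in edgeR's test by either adjustment (camera up, adjusted p = 0.000147; adjusted p = 0.885 with an estimated correlation). Coq10b and Usp2 overlap exons of other genes. The 19 calls became 3, 9 and 8 without vehicle library 1, 2 and 3, and 87 and 7 without tamoxifen library 1 and 3. DESeq2 called 145 and limma-voom 10.

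Transgene males given tamoxifen showed Flrt1 at 244 ± 64.0 CPM (SD, n = 3), risen from 3.62 ± 0.266 after vehicle, a log2 change of 6.08 ± 0.20 (SE; adjusted p = 5.29e-09). Rhpn2 rose by 3.10 ± 0.26, Mycn, a growth transcription factor gene, by 3.05 ± 0.38, the homeobox gene Alx4 by 2.23 ± 0.33 and Lrfn4 by 2.09 ± 0.21. Dkk3, a secreted protein of the Dickkopf family, fell by 4.27 ± 0.45 and Ostn, which encodes the secreted peptide musclin, by 2.19 ± 0.27. Amd1, the decarboxylase that feeds polyamine synthesis, fell from 1898 ± 576 to 606 ± 186 CPM, a log2 change of -1.65 ± 0.25 (adjusted p = 0.00837), and its near-identical copy Amd2 fell by 1.62 ± 0.29. The test called 139 of 15628 genes, 80 higher and 59 lower, with 74 at least 2-fold, and the groups did not overlap in 13.8% of genes (10% by chance).

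By list, 2 of 15 adipocyte markers rose in transgene males, Car3, a carbonic anhydrase that muscle also expresses, by 1.67 ± 0.22 and Plin4 by 0.92 ± 0.16 (camera up, adjusted p = 0.000413; adjusted p = 0.994 with an estimated correlation). Of 29 extracellular matrix genes 1 rose by either adjustment, Postn by 1.61 ± 0.25 (camera up, adjusted p = 1.26e-06; adjusted p = 0.994 with an estimated correlation). Markers of fibro-adipogenic progenitors and fibroblasts moved the same way with a median of 0.24 (camera up, adjusted p = 0.0022) and blood cell markers likewise (camera up, adjusted p = 0.0442), with 0 of 15 and 0 of 8 members past the threshold in edgeR's test by either adjustment. Both had adjusted p = 0.994 with an estimated correlation. Of 13 tendon and myotendinous junction markers 0 passed over all genes in edgeR's test and 5 rose when adjusted over the list alone, among them Col22a1 at 0.65 and Scx, a tendon transcription factor gene, at 0.66 (camera up, adjusted p = 7.19e-07; adjusted p = 0.94 with an estimated correlation). The unfolded protein list had 1 rise of 21, Xbp1 by 0.81 ± 0.11, and the sarcomere list 1 of 30, Myom2 of the M-band by 0.59 ± 0.12. Myom2 lost its call in 12 of 20 alternatives. Of the clock list 0 of 18 passed by either adjustment in edgeR's test (camera adjusted p = 0.724). Of 27 Notch signalling genes and 28 Numb partners 0 passed by either adjustment, and of 11 septins 1, Sept9 at -0.33 ± 0.08, fell when adjusted over the list alone, with camera at adjusted p = 0.909, 0.64 and 0.235. Libraries of these males spread in fibre type, since Myh7 lay at 61.0 to 917 CPM after vehicle and at 9.97 to 759 CPM after tamoxifen. In fits chosen after the data were seen, the count of 139 was 45 without the library lowest in Myh7 of each group and 587 with the 3 lowest Myh7 libraries as a block. In a fit on the 6 transgene males it was 27. It was 68 and 88 without transgene vehicle library 1 and 2, and 69 without transgene tamoxifen library 3. It was 82 and 85 without flox vehicle library 1 and 2, and 85, 80 and 80 without flox tamoxifen library 1, 2 and 3. Rhpn2, Ostn and Plin4 overlap exons of other genes, and reads of Amd1 and Amd2 cannot be separated with certainty.

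In flox males tamoxifen raised Flrt1 from 2.00 ± 0.334 to 214 ± 4.49 CPM (SD, n = 3), a log2 change of 6.73 ± 0.21 (SE; adjusted p = 2.8e-09), Rhpn2 rose by 3.36 ± 0.26 and Car3 by 1.69 ± 0.22. Amd1 fell from 1460 ± 131 to 301 ± 36.1 CPM, a log2 change of -2.28 ± 0.25 (adjusted p = 0.00104), Smox, the spermine oxidase gene, fell by 2.40 ± 0.49 and Dkk3 by 3.48 ± 0.40. Slc7a2, a transporter of cationic amino acids, rose by 2.15 ± 0.16 and the stress gene Gadd45a by 1.77 ± 0.23. Eno1b, an enolase gene nearly identical to Eno1, rose by 4.98 ± 0.40 from 0.247 ± 0.0819 to 7.89 ± 2.42 CPM. The interferon-induced GTPase genes Iigp1 and Tgtp2 fell by 2.17 ± 0.35 and 2.20 ± 0.36. The test called 452 genes of 15628, 211 higher and 241 lower, with 183 at least 2-fold, and the groups did not overlap in 27.8% of genes (10% by chance).

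Denervation and atrophy genes rose in 3 of 25 cases in flox males, Gadd45a, Foxo3 by 0.87 ± 0.15 and Ncam1 by 0.73 ± 0.18, and adjusted over the list alone 3 rose and 1 fell (camera up, adjusted p = 0.0283; adjusted p = 0.847 with an estimated correlation). Of 29 extracellular matrix genes 3 fell, Lamc1 by 0.42 ± 0.10, Col4a1 by 0.88 ± 0.21 and Col4a2 by 0.75 ± 0.17, and 6 when adjusted over the list alone (camera down, adjusted p = 0.000591; adjusted p = 0.847 with an estimated correlation). Over 18 alternatives the call was lost in 6 for Lamc1, 12 for Col4a1 and 9 for Col4a2. Among other genes named for these males, it was lost in 11 for Igf1, 10 for Bst2, 9 for Ncam1, 8 for Smox and 7 for Arntl. It held in each alternative for Gadd45a, Foxo3, Car3, Plin4, Per3 and Sept9. The oestrogen and androgen related list had 3 falls of 15, Amd1, Smox and the growth factor gene Igf1 by 0.74 ± 0.18, and 4 when adjusted over the list alone (camera adjusted p = 0.143). Of 15 adipocyte markers Car3 and Plin4 (by 0.96 ± 0.16) rose by either adjustment (camera up, adjusted p = 0.403). Of 23 cholesterol genes 1 fell over all genes, and adjusted over the list alone 4 fell, among them Msmo1, Sqle and Srebf2 (camera down, adjusted p = 0.0199; adjusted p = 0.498 with an estimated correlation; fry adjusted p = 0.0208). Of 19 interferon response genes 1 fell, Bst2 by 0.82 ± 0.20 (camera down, adjusted p = 0.00251; adjusted p = 0.847 with an estimated correlation). Of 18 clock genes 2 rose over all genes, among them Per3 (adjusted p = 0.0084), and 1, Arntl, fell by 2.07 ± 0.40, and adjusted over the list alone 3 rose and 3 fell. The list's median was 0.29, its mean -0.05 and its camera direction up (adjusted p = 0.282). Sept9, 1 of 11 septins, fell by 0.58 ± 0.08. Vehicle library 3 of these males stood apart, with the heat shock gene Hspa1a at 250 CPM and Arntl at 7.93 CPM. Leaving out vehicle library 1 or 2 gave 145 or 296 genes. Leaving out tamoxifen library 1, 2 or 3 gave 208, 246 or 143, and a fit on the 6 flox males gave 917. Rhpn2, Slc7a2, Gadd45a, Ncam1, Arntl, Col4a1 and Col4a2 overlap exons of other genes, and Eno1b, Amd1 and Tgtp2 have near-identical copies, so their counts are uncertain.

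The tamoxifen responses of transgene and flox males contrast groups with no library in common. Both were estimated in 1 fit of all 12 male libraries with a shared spread. They held 52 genes called higher in both and 40 called lower in both, and 0 called in opposite directions. Independent lists of 80 and 211 higher and of 59 and 241 lower genes would share 1.08 and 0.91 (one-sided exact hypergeometric test, p = 1.5e-79 and 1.25e-59). These p-values take the lists as independent, which a shared fit does not ensure. They also take genes as independent draws, although genes can vary together between libraries. Fitted on their own 6 libraries, transgene males had 27 calls instead of 139, so far fewer genes could be shared. Of the 139 genes called in transgene males, 133 had the same sign in flox males, against 58.1% of all 15628 genes. In females 3 genes were called higher in both genotypes and 1 lower, where independent lists would share 0.0867 and 0.036. Of 186 genes called in transgene females and tested in both, 154 had the same sign in flox females, against 60.8% of all 13886 genes.

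**Figure D2:**
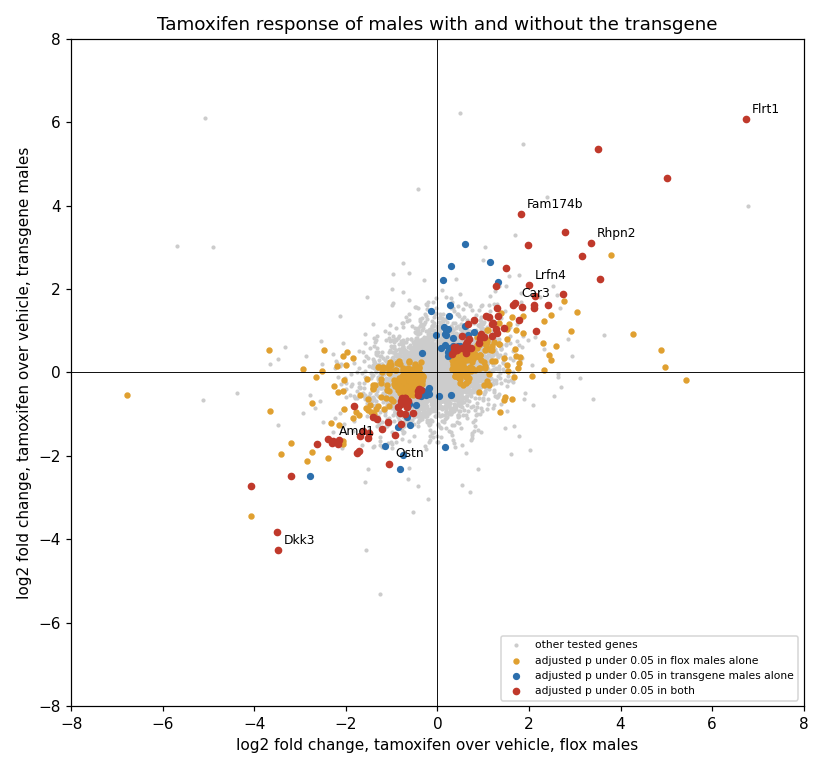
Log2 fold changes, tamoxifen over vehicle, in flox males (horizontal) and transgene males (vertical), a point per gene, coloured by the comparison in which the adjusted p lay under 0.05. Flrt1 lies at 6.73 and 6.08, and Amd1 at -2.28 and -1.65. The sign is the same in flox males for 133 of the 139 genes called in transgene males, against 58.1% of all genes.

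Transgene and flox males were also compared after vehicle, with the treatment of the transgene group taken from its titles. Esr1 was higher in transgene males by 5.38 ± 0.38 on the log2 scale (SE, n = 3 per group; adjusted p = 9.45e-05), at 1088 ± 417 against 26.1 ± 2.71 CPM. Eno1b was higher by 5.07 ± 0.40, the transcription factor gene Cebpd by 2.11 ± 0.24, and Kbtbd12 by 1.86 ± 0.18. Myog was lower by a log2 change of -2.07 ± 0.36, the interleukin receptor gene Il2ra by -2.61 ± 0.44, and the immune regulators Nlrc5 and Irf4 by -1.75 ± 0.30 and -1.70 ± 0.35. The test called 148 of 15628 genes, 60 higher and 88 lower, and the groups did not overlap in 22.6% of genes (10% by chance). Adjusted over the list alone, 6 of 18 proliferation genes were lower, among them the cell division marker Mki67 at -1.18, as were 6 of 19 interferon response genes, 4 of 13 tendon markers and 6 of 8 blood cell markers, while over all genes 0 members of these lists passed in edgeR's test. Camera gave down at adjusted p = 0.00121 for each of these 4 lists (adjusted p = 0.582 with an estimated correlation for proliferation, tendon and blood, and adjusted p = 0.631 for interferon). The 15 adipocyte markers were lower too, with a median of -1.10 and 0 members past the threshold in edgeR's test by either adjustment (camera down, adjusted p = 0.00121; adjusted p = 0.582 with an estimated correlation). Fibroblast markers were lower as well, with a median of -0.24 (camera down, adjusted p = 0.0367; adjusted p = 0.631 with an estimated correlation). These transgene vehicle males are the baseline of the adipocyte, tendon, blood and fibroblast marker changes given for transgene males and for both sexes. Hemoglobin genes among the blood markers are near-identical copies. Without transgene vehicle library 1 or 3 the test called 52 or 59 genes, without flox vehicle library 1 or 2 it called 44 or 63, without the low Myh7 libraries 61, and DESeq2 called 601. Cebpd and Nlrc5 overlap exons of other genes, and Flrt1 did not pass (0.85 ± 0.21, adjusted p = 0.0782).

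The interaction in males asked whether the tamoxifen response differed by genotype. It did in 2 of 15628 genes, Eno1b (log2 difference -4.86 ± 0.49, SE; adjusted p = 0.00478) and Aldh3a1, an aldehyde dehydrogenase gene outside the naming rule and named after its value was seen (-5.61 ± 0.65, adjusted p = 0.00644). Aldh3a1 changed by 5.43 ± 0.40 in flox males and by -0.18 ± 0.47 in transgene males (adjusted p = 2.42e-05 and 0.944). Of 29 extracellular matrix genes 0 passed over all genes in edgeR's test. Adjusted over the list alone 15 had a higher change in transgene males, among them the collagen chaperone gene Serpinh1 at 1.66 ± 0.41, Col1a1 at 1.55 ± 0.46, Postn at 1.35 ± 0.36 and Col4a1 at 1.10 ± 0.29 (camera up, adjusted p = 2.43e-13; adjusted p = 0.527 with an estimated correlation). Tendon markers were higher likewise (camera adjusted p = 1.63e-05; adjusted p = 0.527 with an estimated correlation), with 1 of 13 members, Col22a1 at 1.08, past the threshold when adjusted over the list alone. Interferon response genes had a higher change in transgene males at camera adjusted p = 2.34e-05 (adjusted p = 0.796 with an estimated correlation), with 2 of 19 members, Rtp4 and Bst2, past the threshold when adjusted over the list alone. The unadjusted p lay under 0.05 in 1290 genes, DESeq2 called 79 and limma-voom called 0. Without transgene tamoxifen library 1, flox vehicle library 2, flox vehicle library 3 or flox tamoxifen library 2 edgeR called 4, 4, 8 or 5.

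**Figure D3:**
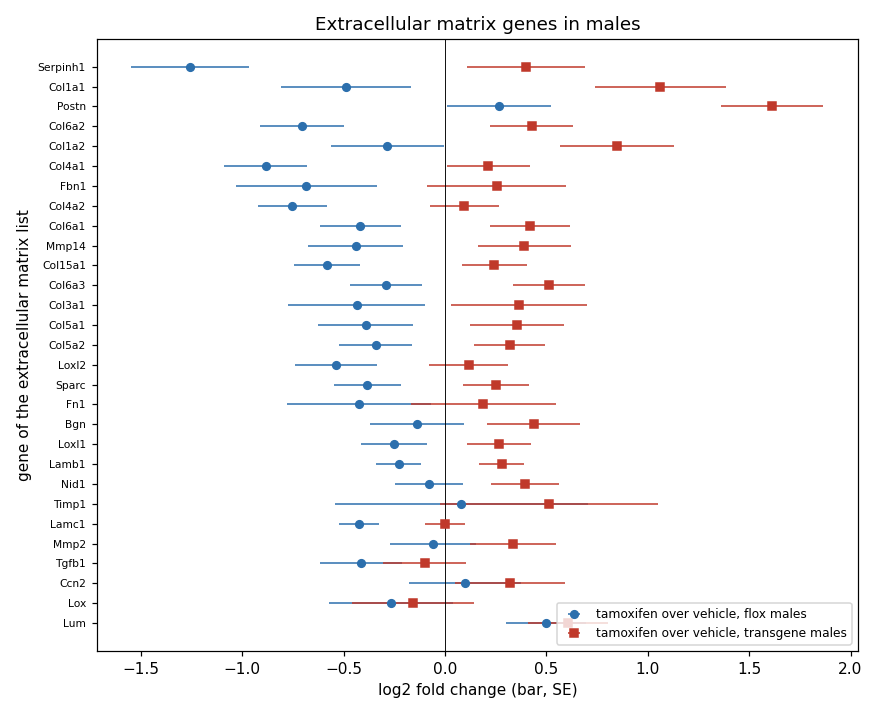
Log2 fold changes, tamoxifen over vehicle, of the 29 extracellular matrix genes in flox males (blue circles) and transgene males (red squares), with bars for the SE. Postn lies at 1.61 in transgene males, and Col4a1 at -0.88 in flox males.

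In females the interaction test by edgeR called 0 of 15182 genes, with 1145 at an unadjusted p under 0.05, against 45 by DESeq2, 1 by limma-voom and 1 with RLE size factors. The smallest p-values belonged to Carns1, which makes the muscle dipeptide carnosine, at -0.80 ± 0.14, Sec14l5 at -0.88 ± 0.16 and the clock gene Bhlhe40 at -1.06 ± 0.20, each at adjusted p = 0.292. All 3 passed with DESeq2 (adjusted p = 0.00139). Of 24 glycolysis and glycogen genes 4 were lower when adjusted over the list alone, Phka1 (unadjusted p = 0.000411), Phkg1 at -0.49 ± 0.11, Ldha at -0.58 ± 0.14 and Tpi1 at -0.42 ± 0.12 (camera down, adjusted p = 0.00133; adjusted p = 0.575 with an estimated correlation). Without transgene tamoxifen library 2, transgene tamoxifen library 3, flox vehicle library 1 or flox tamoxifen library 2 the count was 1, 2, 2 or 2. Transgene and flox females lie in different deposited tables, and each response was taken within its own table. Carns1 and Bhlhe40 overlap exons of other genes.

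Over both sexes, tamoxifen in transgene animals raised Flrt1 by 6.16 ± 0.24 (SE, 6 libraries per treatment; adjusted p = 1.55e-07), Fam174b by 3.78 ± 0.42, Rhpn2 by 2.52 ± 0.23 and Lrfn4 by 1.92 ± 0.17. It raised Ucp1, the uncoupling protein of brown fat, by 4.21 ± 0.53, from 0.0663 ± 0.0610 to 1.51 ± 1.07 CPM in females and from 0.0798 ± 0.0758 to 1.29 ± 0.642 CPM in males. Itga4 fell by 1.51 ± 0.21, Ostn by 2.42 ± 0.36 and Mib1, a ubiquitin ligase of Notch ligands that is not on the Notch list, by 1.01 ± 0.16 (adjusted p = 0.0127). The test called 200 of 15677 genes, 107 higher and 93 lower. Of 15 adipocyte markers Ucp1, Plin4 and Car3 rose, and adjusted over the list alone also Lep at 2.59 and Pparg at 0.68 (camera up, adjusted p = 1.77e-07; adjusted p = 0.106 with an estimated correlation; fry adjusted p = 0.00809). Of 13 tendon markers Scx rose by 0.61 ± 0.12 and, adjusted over the list alone, Col12a1 at 0.94 (camera up, adjusted p = 2.31e-05; adjusted p = 0.799 with an estimated correlation). Notch signalling and Numb partners had 0 members past the threshold by either adjustment in edgeR's test, at camera adjusted p = 0.509 and 0.889. The count of 200 was 100, 81 and 106 without female vehicle library 1, 2 and 3, 121, 87 and 101 without female tamoxifen library 1, 2 and 3. It was 106 and 127 without male vehicle library 1 and 3, 119 without the low Myh7 males and 574 by DESeq2.

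The separate transgene comparisons of females and males, which share no library, had 13 genes called higher in both and 7 lower in both, with 1 in opposite directions. Flrt1, Rhpn2, Syt12, Lrfn4 and Plin4 were higher and Dkk3 was lower in both. Independent lists of 85 and 75 higher and 99 and 49 lower genes would share 0.464 and 0.353 (one-sided exact hypergeometric test, p = 6.93e-16 and 5.45e-08). These p-values take genes as independent draws, and genes that vary together between libraries can make them too small. Transgene females and flox males shared 19 higher and 26 lower genes, against 1.25 and 1.59 for independent lists, with 2 in opposite directions. With males fitted on their own 6 libraries, the 20 genes shared by transgene females and males in the same direction became 6. In a score of the clock list, tamoxifen minus vehicle was 1.54 ± 0.349 (SE) in transgene females, 1.33 ± 0.175 in flox females, 1.34 ± 0.517 in flox males and 0.0248 ± 0.141 in transgene males.

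**Figure D4:**
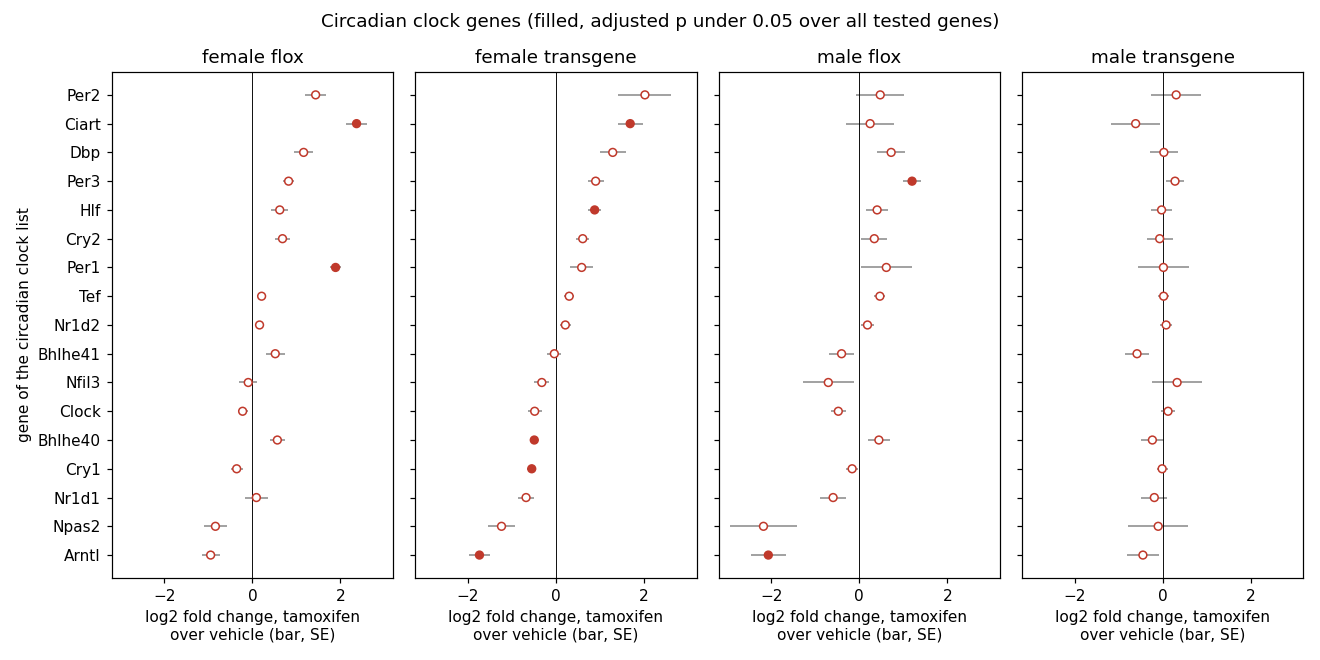
Log2 fold changes, tamoxifen over vehicle, of circadian clock genes in the 4 comparisons of sex and genotype, with bars for the SE and filled points where the adjusted p over all genes lay under 0.05. Arntl lies at -1.74 in transgene females, -0.95 in flox females and -2.07 in flox males, and in transgene males 0 points are filled.

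A direct test of the difference between the sexes in the transgene response called 4 of 15677 genes. Kcne1l changed more in females by 4.08 ± 0.60 (SE; adjusted p = 0.0444) and the transcription factor gene Tfcp2l1 by 1.98 ± 0.23 (adjusted p = 0.0143), while the glycoprotein hormone gene Stc2 differed by -2.90 ± 0.39 (adjusted p = 0.0404) and the interferon-induced GTPase gene Irgm2 by -1.85 ± 0.27 (adjusted p = 0.0444). Stc2 had means of 10.4 and 4.98 CPM in females after vehicle and tamoxifen and of 1.43 and 5.06 CPM in males. Since females and males lie in different deposited tables, these levels cannot be compared between the sexes. Of 19 interferon response genes 0 passed over all genes in edgeR's test and 10 had a lower change in females when adjusted over the list alone, such as Ifit3 at -1.58 ± 0.44 (camera down, adjusted p = 6.73e-07; adjusted p = 0.637 with an estimated correlation). Leaving out female vehicle library 1, 2 or 3 gave 0, 1 or 0 calls, and female tamoxifen library 1, 2 or 3 gave 2, 0 or 9. Leaving out male vehicle library 1, 2 or 3 gave 2, 1 or 7, and male tamoxifen library 1, 2 or 3 gave 1, 2 or 0. Irgm2 and Tfcp2l1 overlap exons of other genes.

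The same difference in flox animals, a comparison added after the data were seen, called 43 of 16194 genes, 18 with a higher and 25 with a lower change in females. Smox and Amd1 of polyamine metabolism differed by 2.71 ± 0.31 and 2.02 ± 0.18 (SE; adjusted p = 0.00699 and 9.92e-05). Amd1 had means of 72.3 ± 1.82 and 60.9 ± 11.3 CPM (SD, n = 3) in females after vehicle and tamoxifen and of 1421 ± 124 and 296 ± 34.8 CPM in males. Females and males lie in different deposited tables, so these levels cannot be compared between the sexes. The tables can differ widely, with mt-Tp at 0.103 to 1.03 CPM in females and 68.9 to 113 CPM in males. Slc7a2 differed by -2.36 ± 0.23, Gadd45a by -1.90 ± 0.21, Foxo3 by -0.83 ± 0.15 and Sesn1, a stress response gene, by -0.98 ± 0.17. Both the denervation list and the p53 list had 2 members lower over all genes, at camera adjusted p = 0.187 and 0.491. Without female vehicle library 3, female tamoxifen library 1 or female tamoxifen library 3 the count was 26, 136 or 28. Without male vehicle library 1, male vehicle library 2, male tamoxifen library 1 or male tamoxifen library 3 it was 22, 71, 25 or 28. Slc7a2 and Gadd45a overlap exons of other genes, and Amd1 has a near-identical copy.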

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

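Of the tests in this part, those on a variant, on a loss that tamoxifen prevents and on the difference between the sexes in flox animals were chosen only after the result was seen.

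The test of a difference between groups called 2 genes for the tamoxifen response of transgene and flox males, Eno1b (-4.86) and Aldh3a1 (-5.61). Eno1b lay at 0.240 ± 0.0784 CPM (SD, n = 3) in flox vehicle males, against 7.65 ± 2.25 in flox tamoxifen males and 8.18 ± 0.515 and 8.88 ± 3.76 in transgene males after vehicle and tamoxifen. Reads shared with Eno1 alone would keep the ratio of the genes alike, but the lowest ratio of Eno1b to Eno1 in the other 9 male libraries was 21.4 times the highest in the 3 flox vehicle males, which argues against them. For a loss in vehicle animals that tamoxifen prevents, 3 tamoxifen libraries of 12 lay under 0.5 CPM. All 3 were female, and male tamoxifen libraries lay at 5.98 to 13.2 CPM, so these 3 cannot decide the question for flox males. Transgene vehicle males showed no such loss, at 7.60 to 8.56 CPM. A variant that segregates between animals stays a candidate explanation, since 4 of 12 female libraries lay under 0.5 CPM, 3 of them after tamoxifen, and no genotype was read.

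Among 100 splits of the male libraries for this test, 16 called 2 genes or more, the real one included. A split that mixes the labels of 1 genotype more than the other reads a response as a difference. The share therefore does not measure chance, which was not excluded for the count. Of the 100 splits, 52 exchange most treatment labels of 1 genotype alone, which turns the difference of the responses toward their sum; 9 of the 16 are among these and 7 among the others, a division made after the splits were seen. The highest other count, 683, came from exchanging all treatment labels of flox males, which by construction adds the 2 responses instead of subtracting them.

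The test of a difference between females and males called 4 genes for the response of transgene animals: Kcne1l (4.08), Tfcp2l1 (1.98), Stc2 (-2.90) and Irgm2 (-1.85), as female minus male log2 change. Among 100 splits 8 called 4 genes or more. As for the male interaction, this share does not measure chance, which was not excluded for the count. Of the splits, 53 exchange most treatment labels of 1 sex alone, with 4 of the 8 among these and 4 among the others. The highest other count, 532, came from a split that exchanged transgene male vehicle library 3 with tamoxifen library 1 and female vehicle library 3 with tamoxifen library 2, which points to a structure of the samples.

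The same test called 43 genes for the response of flox animals. Higher changes in females were named for Smox (2.71), Amd1 (2.02), Amd2 (1.93), Gdap1 (1.79), Smtnl2 (1.58), Npnt (1.31), Prkcd (1.30), Cdk19 (1.24), Pdgfb (1.18) and Pkdcc (0.95). Lower changes in females were named for Slc7a2 (-2.36), Rhpn2 (-2.09), Gadd45a (-1.90), Gpx3 (-1.77), Adh1 (-1.66), Pik3r1 (-1.58), Mxra8 (-1.57), Neu2 (-1.55), Abhd18 (-1.54), Angpt1 (-1.40), Sesn1 (-0.98) and Foxo3 (-0.83). Among 100 splits 7 called 43 genes or more. This share likewise does not measure chance, which was not excluded for the count. Here 51 splits exchange most labels of 1 sex alone, with 4 of the 7 among these and 3 among the others. The highest other count, 334, came from a split that exchanged all treatment labels of flox males and also female vehicle library 2 with tamoxifen library 2. In these 2 comparisons females and males also differ in deposited table, so sex and table cannot be told apart in the level of a gene, while each response was taken within a table. For the interaction in females, where 0 genes were called, the splits test nothing, since all 100 reach a count of 0 by construction; the highest other count was 82.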

How the results depend on the processing

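Of 186 named calls, 76 stayed past the threshold in every alternative, 110 did not in some, and 0 reversed. Of 23 named results not past it, 3 passed in some alternative, all in the female interaction: Carns1 in 3, Sec14l5 in 2 and Bhlhe40 in 2 of 17. Counts are in the order transgene females, flox females, transgene males, flox males, vehicle males, female interaction, male interaction, both sexes, sex difference in transgene and in flox animals. DESeq2 called 679, 145, 328, 871, 601, 45, 79, 574, 108 and 268 genes. Without the low-count filter the counts were 941 and 329 in transgene and flox females, 221 in transgene males, 327 in vehicle males, 20 and 38 for the interactions, and 46 and 757 for the sex differences. Limma-voom called 10 in flox females, 1 and 0 for the interactions, RLE size factors gave 1 for the female interaction, and the stricter filter gave 1 for the sex difference in transgene animals. With all 12 female libraries in the fit transgene females had 417 calls, with only their own 6 libraries transgene males had 27 and flox males 917, and with all 24 libraries both sexes had 552 and the sex difference in transgene animals 32. Without the low Myh7 transgene males, a choice made after the data were seen and by a value measured in them, the counts were 45 in transgene males, 61 in vehicle males, 1 for the male interaction, 119 over both sexes and 2 for the sex difference in transgene animals. With the 3 lowest Myh7 libraries as a block, chosen likewise, transgene males had 587. The 20 calls shared by transgene females and males became 47 at a threshold of 0.10 and 6 with males fitted on 6 libraries. With an estimated correlation camera called 0 lists in all 10 comparisons, and fry called 1 in flox males, 1 over both sexes and 0 in the other 8. Leaving out 1 library gave 37 to 215, 3 to 87, 68 to 151, 143 to 644, 44 to 204, 0 to 2, 2 to 8, 81 to 176, 0 to 9 and 22 to 136 calls. Numb in transgene males, not past the threshold, reversed to -0.004 with DESeq2, -0.002 with limma-voom, -0.003 with RLE size factors, -0.003 without the filter, -0.001 with the stricter filter and -0.001 on 6 libraries, and ranged from -0.043 to 0.063 on leaving out 1 library. Further ranges across 0 were -0.039 to 0.076 for Numb in vehicle males, -0.042 to 0.091 for Numb and -0.104 to 0.181 for Numbl in the female interaction, -0.026 to 0.292 for Numbl in the sex difference of transgene animals, and -0.113 to 0.011 for Numb and -0.176 to 0.007 for Numbl in that of flox animals. Flox females share replicate numbers between treatments, but libraries of the same number correlated at -0.200, -0.0330 and -0.101 after group means were removed, so the numbers do not show pairs, and a fit with the number as a block called 15 genes against 19, with 8 shared, and no longer called Smarca1 and Fosl2. Fits that leave out 1 library hold fewer libraries by construction, and for the other changes the cause was not tested.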

Other observations

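Of the tests in this part, those weighing explanations for the 2 patterns and the list tests of the sex difference in flox animals were chosen only after the result was seen. The bound for the clock phase in males was changed after its first version came out undecided, and the tests on genes called in transgene animals were added after the first tests were seen.

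Further gene groups passed in camera with the preset correlation, although other splits of the libraries often called as many lists. In transgene females nuclear genes of oxidative phosphorylation (adjusted p = 0.00109), Schwann cell and nerve markers (adjusted p = 0.00339), blood cell markers (adjusted p = 0.0205), tendon markers and neuromuscular junction genes (each adjusted p = 0.0362) were higher after tamoxifen and fast fibre genes lower (adjusted p = 0.0278), each at adjusted p = 0.762 with an estimated correlation. In flox females glycolysis genes (adjusted p = 0.011) and adipocyte markers (adjusted p = 0.0074) were higher and interferon response genes (adjusted p = 0.0074) and immune cell markers (adjusted p = 0.044) lower, each at adjusted p = 0.885 with an estimated correlation. In flox males proteasome genes were higher (adjusted p = 0.0239; adjusted p = 0.847 with an estimated correlation) and proliferation genes lower (adjusted p = 0.00251; adjusted p = 0.6 with an estimated correlation). In vehicle males calcium handling genes (adjusted p = 0.00133), sarcomere genes (adjusted p = 0.0229) and clock genes (adjusted p = 0.0288) were higher in transgene animals, each at adjusted p = 0.582 with an estimated correlation. Proteasome genes (adjusted p = 0.00121) and fast fibre genes (adjusted p = 0.0458) were higher there too. Fatty acid oxidation genes (adjusted p = 0.00121), immune cell markers (adjusted p = 0.0213), fibroblast markers (adjusted p = 0.0367), unfolded protein genes (adjusted p = 0.0458) and mitochondrially encoded genes (adjusted p = 0.0471) were lower, and all of these 7 had adjusted p = 0.631 with an estimated correlation. The unfolded protein list had a median of -0.28 and a mean of -0.67, and its member Hspa1a lay at 250 CPM in flox vehicle library 3 against 10.7 and 7.05 in the other 2.

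In the female interaction slow fibre genes (adjusted p = 0.00133), fatty acid oxidation genes (adjusted p = 0.00815) and Schwann cell markers (adjusted p = 0.0157) had higher changes in transgene animals in camera. Interferon response genes (adjusted p = 0.00426), immediate early genes (adjusted p = 0.00463), fast fibre genes (adjusted p = 0.0141), proliferation genes (adjusted p = 0.0188) and clock genes (adjusted p = 0.0277) had lower ones, each of these 8 at adjusted p = 0.617 with an estimated correlation. Cholesterol genes (adjusted p = 0.0277) and p53 genes (adjusted p = 0.0276) were lower at adjusted p = 0.575 with an estimated correlation. In the male interaction fibroblast markers (adjusted p = 0.0102) and immune cell markers (adjusted p = 0.0343) were higher and slow fibre genes lower (adjusted p = 0.025), each at adjusted p = 0.796 with an estimated correlation. Cholesterol genes (adjusted p = 0.0203; adjusted p = 0.527 with an estimated correlation), septins (adjusted p = 0.0343; adjusted p = 0.742 with an estimated correlation) and oxidative phosphorylation genes (adjusted p = 0.0495; adjusted p = 0.849 with an estimated correlation) were higher, and denervation genes lower (adjusted p = 0.0203; adjusted p = 0.744 with an estimated correlation). Over both sexes blood cell markers (adjusted p = 0.00153; adjusted p = 0.799 with an estimated correlation) were higher, as were oxidative phosphorylation genes (adjusted p = 0.00663), extracellular matrix genes (adjusted p = 0.00709) and Schwann cell markers (adjusted p = 0.0333), the last 3 at adjusted p = 0.835 with an estimated correlation, and proliferation genes were lower (adjusted p = 0.0493; adjusted p = 0.804 with an estimated correlation). In the sex difference of transgene animals slow fibre (adjusted p = 0.00514), fatty acid oxidation (adjusted p = 0.00777) and oxidative phosphorylation genes (adjusted p = 0.0279) had higher changes in females and extracellular matrix genes lower ones (adjusted p = 0.00357), each at adjusted p = 0.898 with an estimated correlation. Denervation genes (adjusted p = 0.0122; adjusted p = 0.275 with an estimated correlation) and neuromuscular junction genes (adjusted p = 0.0273; adjusted p = 0.637 with an estimated correlation) were higher there. In that of flox animals oxidative phosphorylation (adjusted p = 0.000113), extracellular matrix (adjusted p = 0.000232), proliferation (adjusted p = 0.00039), immediate early (adjusted p = 0.0118), cholesterol (adjusted p = 0.0153) and oestrogen and androgen related genes (adjusted p = 0.0422) had higher changes in females and slow fibre genes lower ones (adjusted p = 0.0204), each at adjusted p = 0.903 with an estimated correlation.

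The first pattern is a tamoxifen response shared by animals with and without the transgene, for which flox libraries that carry the transgene are argued against, since the highest Esr1 value of the 12 flox libraries was 42.1 CPM and the lowest of the 12 transgene libraries 399 CPM. A response to tamoxifen that needs no transgene fits the 139 genes called in transgene males, whose median change in flox males, signed by direction, was 0.796 against 1.07 in transgene males. For genes called in transgene females, in flox males and in flox females the medians in the other genotype were 0.287 against 0.773, 0.319 against 0.808 and 0.644 against 1.39, between the bounds set for and against that explanation, so it stays open for these genes. Each set was picked in the genotype named first, where its changes can be inflated, and this holds for the 139 genes too. A different clock phase of tamoxifen and vehicle animals as the cause in males is argued against by a clock score shift of 0.0248 ± 0.141 (SE) in transgene males against 1.34 ± 0.517 in flox males. The flox vehicle males scored 0.855, 2.08 and 2.57, so the size of the flox shift depends in part on vehicle library 1.

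The second pattern is the difference of clock genes between tamoxifen and vehicle libraries. Tamoxifen alone in every group is argued against, but only weakly. The mean shift of the clock score in the other 3 pairs exceeded that in transgene males by 1.38 (SE 0.258). Transgene males were set apart after their shift was seen, and the other 3 pairs span all 3 deposited tables. The SE takes no account of that choice. Among males, which lie in 1 deposited table, the shift in flox animals exceeded that in transgene animals by 1.32 (SE 0.536), a weaker contrast. It rests on 3 libraries per group, with an SD of 0.884 in flox vehicle males. The interaction test in males called Eno1b and Aldh3a1 alone and no clock gene. Different dissection times of the treatment groups stay a candidate explanation, but no dissection time is given in the sources used here. The changes of the 18 clock genes in transgene females and flox males, which share no library, had r = 0.784. Those of transgene females had r = 0.86 with flox females and r = 0.221 with transgene males. Any cause that shifts the clock in several pairs would give such correlations, so they do not favour dissection times over tamoxifen.

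Splits of the libraries into other groups of the same size give a further check. For single comparisons 10 splits exist, too few for a share under 0.05. Transgene females had 187 calls, flox males 452 and vehicle males 148, each against 1 as the highest other count, and 1 split in each was as large, the real one. Flox females had 19 calls against 15 as the highest other count, with 1 split as large. Transgene males had 139 calls, with 2 splits as large and 554 as the highest other count, from exchanging vehicle library 3 with tamoxifen library 1. That split parts libraries with 415, 917 and 759 CPM of Myh7 from those with 61.0, 214 and 9.97, which points to a structure of the samples. Of 100 splits, 1 reached the 200 calls over both sexes and 1 the 20 calls shared by transgene females and males, the real one each time, with 1 as the highest other count for both. Camera with the preset correlation called as many lists as in the real grouping in 5, 6, 8, 8 and 4 of 10 splits. These are transgene females, flox females, transgene males, flox males and vehicle males. For the female and male interactions this held in 23 and 36 of 100 splits, and over both sexes in 56. For the sex differences in transgene and flox animals it held in 57 and 67. The number of lists called therefore does not set the real groups apart.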
